A study of Homo sapiens with 18 samples.

How the data were processed

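Total RNA was taken from sucrose density gradient fractions of HL60 cells, 9 fractions of control cells and 9 of cells treated with VitD3, and each sample was labelled with Cy3 and hybridised to 1 Agilent human miRNA array (version 3 design), with 100 ng of RNA per array per the labels. The deposited scanner files hold spot intensities from Agilent Feature Extraction, version 10.5.1.1 for fractions 3 and 8 to 11 and version 10.7.3.1 for fractions 4 to 7, per the file headers. The processed intensity is background-subtracted and not scaled between arrays. The deposited value table of the series holds 177 miRNAs as a score, a z-score of each miRNA over the 18 arrays judging by the values, with row means within 0.00444 of 0. The medians of its columns ran from -0.54 to 1.66, and the scale and normalization before the z-score are not given in the sources used here. Array positions were annotated on hg18 per the file headers, while the gene table used here is of another build (GRCh38), so no coordinates are printed and miRNA names are those of the array design. The gene table served only to find which miRNA genes neighbour each other, and 91 of the 102 tested names matched it.

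Each miRNA had 1 to 4 probes and each array 15024 probe spots for 851 human and 88 viral miRNAs. Control spots and spots with outlier marks were left out, spots of a probe were averaged, and the mean over probes was taken on the linear scale. A miRNA was detected on an array when over 0.5 of the spots of any of its probes were well above background. Arrays were scaled to the 75th percentile of the 18 human miRNAs detected on all arrays, values were raised to a floor of 5.37 (the median over arrays of the lowest scaled value of a detected miRNA), and log2 was taken. The test covered 102 human miRNAs detected on 6 or more arrays, and 23.6% of their values lay at the floor, where differences are understated. No saturated spots were present. The number of arrays limits the precision.

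Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) and Benjamini-Hochberg adjustment at 0.05. The treatment comparison had fraction as a factor, the trend was a slope per fraction number with treatment as a covariate, and the trend difference was the interaction of treatment and fraction number. Slide 1 held fraction 3, slide 2 fractions 4 to 7 and slide 3 fractions 8 to 11, with both treatments on each slide, so slide is contained in the fraction factor. Lists were tested with camera at a preset correlation of 0.01 and at an estimated one, and with fry, where 3 or more members were tested. Values per array, and list medians over fractions, were compared by exact permutation of signs over 9 fractions. The self-test on simulated values of the 102 miRNAs called 18 of 20 treatment differences of 0.75 log2 units, 20 of 20 of 1.5 and 1 of 62 unchanged miRNAs. For slopes adding up to 0.75 and 1.5 it called 8 and 18 of 20, and for trend differences 1 and 4 of 20. The slope simulation used equal fraction means and the residual spread of the fit with fraction as a factor. It thus left out the real scatter between fractions and slides, and its counts for slopes do not give the sensitivity in these data. In all 3 simulations noise was independent between arrays, and values were not raised to the floor after changes were added. The counts for treatment differences thus leave out the loss at the floor and may overstate the sensitivity.

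The groups, tests, lists, alternatives and the naming rule were fixed before the data were examined. Named in the treatment comparison were the 12 largest differences in each direction with an adjusted p under 0.05 and the same sign in 8 or more of 9 fractions, plus a fixed set of 16 miRNAs known from myeloid cells. For the trend the 10 largest slopes in each direction with the same sign in both treatments were named, and for the trend difference the 5 largest in each direction. Up to 4 members of each list were added by size of their value. Alternatives covered the scaling (none, all human miRNAs, quantile), normexp background correction with an offset of 50, the summary per miRNA, the filter, the floor, the variance model, the value table, each fraction left out and slide. Normexp used the median spot signal, since a mean signal column was not among those used here. Figures were drawn with matplotlib 3.10.9. Probes of viral miRNAs, of which 0 to 6 were detected per array, were not tested.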

Results

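The microRNA (miRNA) content of sucrose gradient fractions was measured in HL60 cells, a human promyelocytic leukaemia line that can mature towards monocytes when given vitamin D3. The series comprised 18 arrays, 9 from proliferating control cells and 9 from cells treated for 72 h with VitD3. Each array held the RNA of 1 gradient fraction, numbered 3 to 11, of 1 treatment, so that every fraction had 1 control and 1 VitD3 array. The labels named no separate cultures or gradients, and did not say which end of the gradient was light. A p-value over fractions therefore measures how steady a difference was from fraction to fraction, not how it varied between cultures.

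The array carried probes for 851 human miRNAs, of which 205 were detected on at least 1 array, 18 were detected on all 18 arrays and 102 were tested. Signal was strongest in fractions 3 and 4. The 75th percentile of the unscaled signal of the 18 miRNAs seen on every array was 1432 in control fraction 3 and 809 in VitD3 fraction 3, against 32.2 and 56.2 in fraction 11. The number of detected miRNAs ranged from 28 in control fraction 11 to 151 in control fraction 4. Between treatments, the signal differed by 0.10 ± 0.87 log2 units (mean VitD3 minus control ± SD, n = 9 fractions, exact two-sided permutation p = 0.734). This mean hides an ordered change. The signal was lower in VitD3 in each of fractions 3 to 8 and higher in each of fractions 9 to 11. The number of detected miRNAs differed by -5.44 ± 22.2 (SD, n = 9, exact two-sided permutation p = 0.488, higher in VitD3 in 3 of 9 fractions). The smallest p that sign changes over 9 fractions allow is 0.0039. The VitD3 fraction 9 array stood apart, with a negative control signal of 142 against 24.3 to 37.6 on the other arrays.

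**Figure D1:**
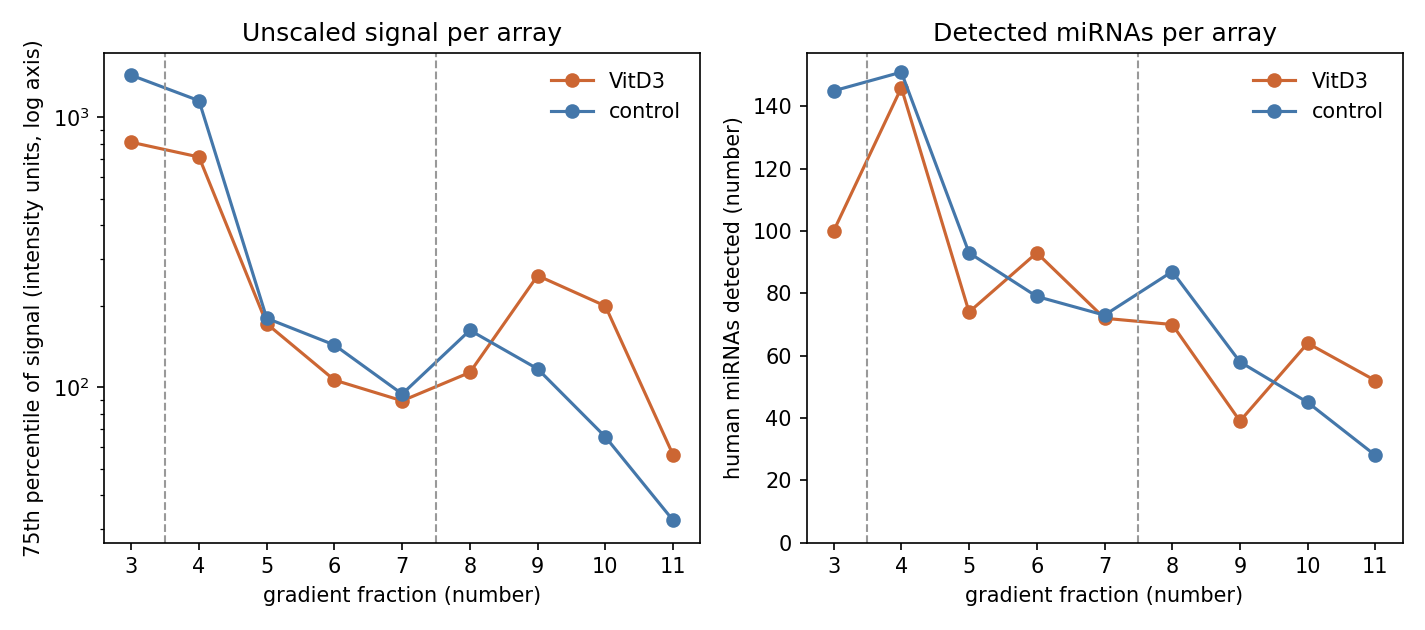
The left panel shows the 75th percentile of the unscaled signal of the 18 miRNAs detected on every array (intensity units, log axis) and the right panel the number of human miRNAs detected, against gradient fraction, with 1 point per array and dashed lines where the slide changes. Control signal lay at 1432 in fraction 3 and 32.2 in fraction 11, and VitD3 signal at 809 and 56.2.

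The comparison of VitD3 with control asked which miRNAs differed during the transition from myeloblast to monocyte, whatever the fraction. Members of the miR-17-92 family, a growth-promoting group encoded by a polycistronic gene and its paralogs, were lower after VitD3. The miRNA miR-92a differed by -1.49 ± 0.23 (log2, SE, n = 9 fractions per treatment), miR-18b by -1.44 ± 0.17, miR-19b by -1.29 ± 0.15 and miR-20a by -1.27 ± 0.14, each lower in 9 of 9 fractions. In the other direction, let-7e differed by 2.18 ± 0.23 and was higher in 9 of 9 fractions. It was well above background on 1 control array and on 8 VitD3 arrays, so the size of the difference depends on the floor (2.97 with the floor lowered to 0.25 of its value). Both arms of the miR-378 hairpin, which lies in an intron of the metabolic coactivator gene PPARGC1B, were also higher, miR-378 by 1.25 ± 0.24 in 9 of 9 fractions and miR-378* by 1.27 ± 0.25 in 8 of 9. With normexp, which adds an offset, these 3 differences were 0.18 (adjusted p = 0.512) for let-7e, -0.00899 for miR-378 and 0.0366 for miR-378*.

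In all, 4 of the 102 tested miRNAs rose and 16 fell with VitD3 at a limma adjusted p under 0.05, and 33 had an unadjusted p under 0.05. The adjusted p was 3e-05 for let-7e and miR-20a, 3.09e-05 for miR-18b and miR-19b, 0.000479 for miR-92a, 0.00277 for miR-378 and 0.00286 for miR-378*. The remaining miRNA that rose was miR-21, a broadly expressed miRNA that is abundant in mature myeloid cells, at 0.77 ± 0.21 (adjusted p = 0.0173), higher in 6 of 9 fractions and at the floor on both arrays of the others. It was detected in 5 of the 6, and in fraction 9 (1.58) on neither array, where the VitD3 array had high background (0.72 and adjusted p = 0.0345 without that fraction). Outside the family of miR-17-92, miR-181a, known from early blood progenitors and lymphocytes, fell by 1.01 on the log2 scale (adjusted p = 0.00286), miR-130b by 0.86, miR-29c by 0.79, miR-148a by 0.60 and miR-29a by 0.53. The probe named miR-1308, a sequence since traced to transfer RNA, fell by 0.76 (adjusted p = 0.0449), miR-1915, a G-rich sequence, by 0.73 and let-7b by 0.58. The last 2 of these and miR-17* (-0.88) fall outside the fixed naming rule and were chosen after their values were seen.

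Of the 12 tested members of the miR-17-92 list, 0 rose, 8 fell and 4 did not pass, and 9 fell when adjusted over the list alone. The list's median was -1.04, which is 0.80 below the median of all tested miRNAs (-0.24), and it was -1.09 without scaling and -0.36 with normexp, the smallest of the scalings and background corrections run. The other called members were miR-18a (-1.15), miR-17 (-1.11), miR-20b (-0.96) and the star strand miR-17* (-0.88). Members that did not pass were miR-19a (-0.66), miR-106b (-0.38), miR-25 (-0.33) and miR-93 (-0.33). The median of the list was below 0 in 9 of 9 fractions (mean -0.94 ± 0.52 SD, exact permutation p = 0.0039 over 9 fractions, 0.0215 adjusted over lists). Unscaled, it was below 0 in 6 of 9 fractions (mean -0.91 ± 1.08 SD, exact permutation p = 0.0469), and was 0.88 in fraction 9, 0.41 in fraction 10 and 0 in fraction 11. Camera with a preset correlation called the list down (adjusted p = 7.21e-06), and the call was lost with an estimated correlation (adjusted p = 0.473), while fry gave an adjusted p of 0.00102. Close relatives such as miR-17, miR-20a and miR-106b share most of their sequence, and hybridisation of 1 to the probe of another cannot be ruled out on this array.

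**Figure D2:**
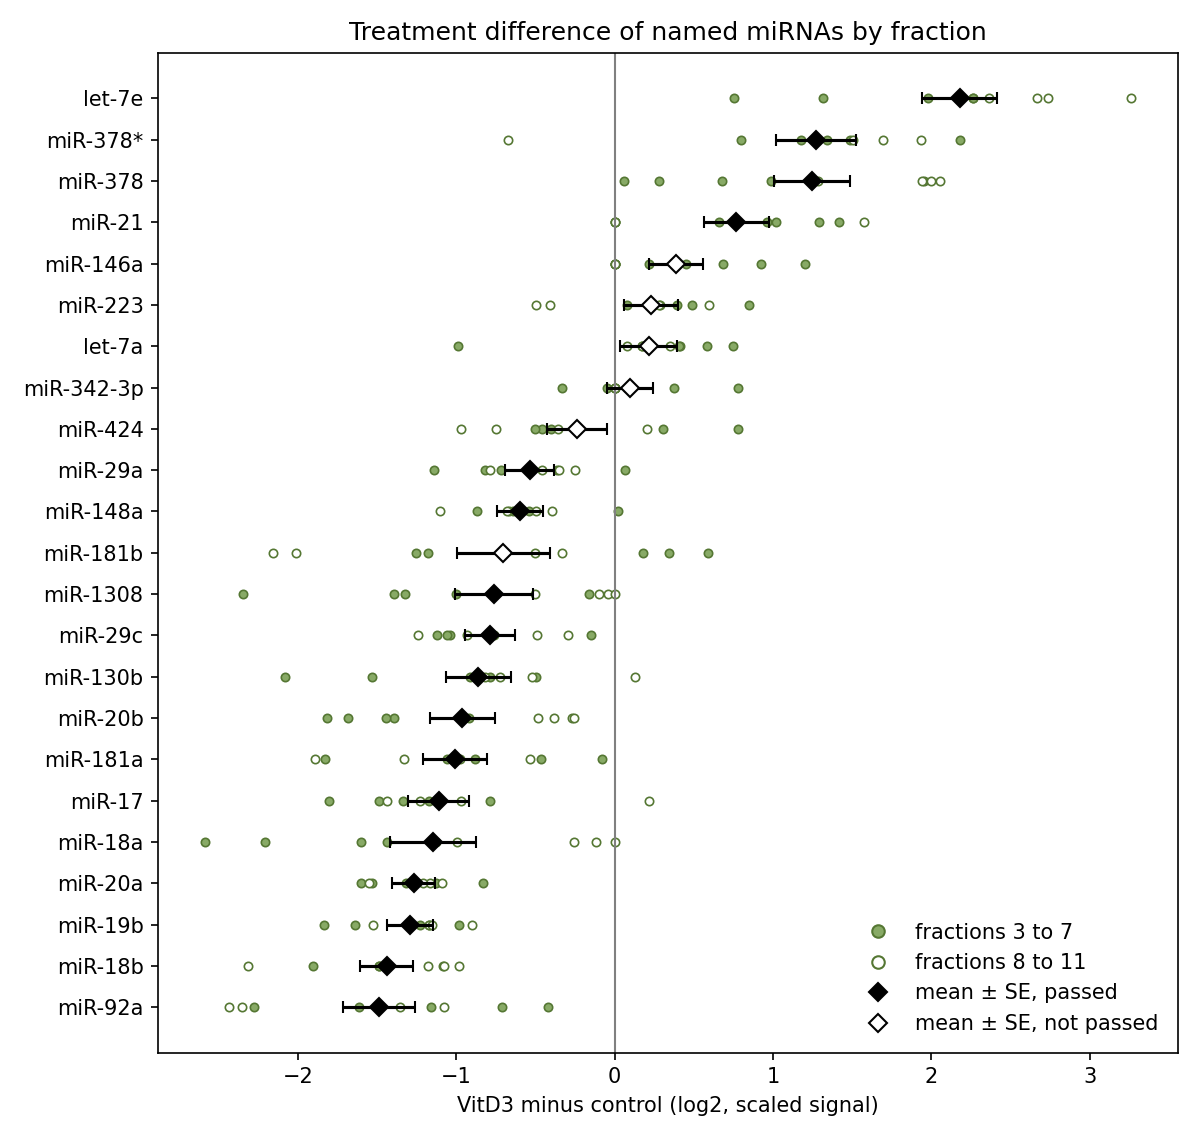
VitD3 minus control difference (log2 of scaled signal) of each miRNA named in this comparison, with 1 point per fraction (filled for fractions 3 to 7, open for 8 to 11) and a diamond with bar for the mean ± SE, filled where the limma adjusted p was under 0.05. The values of let-7e lie to the right of 0 in 9 of 9 fractions with a mean of 2.18, and those of miR-92a to the left in 9 of 9 with a mean of -1.49.

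Among 9 tested let-7 members, a family that restrains growth, let-7e rose, let-7b fell and 7 did not pass, with the same counts adjusted over the list alone. The abundant member let-7a differed by 0.22 ± 0.18 (adjusted p = 0.409). For the list, fry found change in either direction (mixed adjusted p = 1.06e-04) but no balance towards one (0.248). Of 3 tested miR-29 members, 2 fell and miR-29b (-0.24) did not pass, with 2 adjusted over the list alone. In each of fractions 3 to 7, the only ones where it was detected, miR-29b was lower in VitD3 (-1.05 to -0.32). Its difference of 1.55 in fraction 9 came from the VitD3 array with high background. The median of the miR-29 list was below 0 in 9 of 9 fractions with scaling and in 6 of 9 without (unscaled exact permutation p = 0.102 over 9 fractions). Its fry adjusted p was 0.0117, its camera adjusted p 0.394 and, over lists, its exact permutation p 0.0215. Of 3 tested miR-181 members, miR-181a fell, miR-181b differed by -0.70 ± 0.29 (adjusted p = 0.12) and miR-181d by -0.19, and 2 fell adjusted over the list alone.

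Of the list of miRNAs linked to monocytes, 6 members were tested. Of these, miR-21 rose and miR-29a fell, also adjusted over the list alone, and 4 did not pass, among them miR-146a, an inflammatory regulator, at 0.39 ± 0.17 (adjusted p = 0.137) and miR-342-3p at 0.10 ± 0.15. For miR-146a, 11 values lay at the floor, and it was higher in 5 fractions and lower in 0, so its size depends on the floor. The values of miR-424 were -0.24 ± 0.19. Of 7 tested myeloid miRNAs, 0 passed, also adjusted over the list alone. Among them miR-223, the characteristic miRNA of granulocytes and monocytes, differed by 0.23 ± 0.17 (adjusted p = 0.359, higher in 7 of 9 fractions) and miR-142-3p by -0.42 ± 0.15 (adjusted p = 0.0716). Too dim to test were miR-155, detected on 2 control arrays and 0 VitD3 arrays, miR-22, detected on 0 control and 3 VitD3 arrays, and miR-26a, miR-32 and miR-125b. Among the rest, 0 of 4 tested miR-15/16 members, 0 of 3 of miR-23/24/27, 0 of 1 of miR-30 and 0 of 1 of miR-221 and its relative passed, and adjusted over the list alone 1 member of miR-23/24/27 fell.

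Markers of other cell types were scarce. From the epithelial list and the erythroid and platelet list 0 members were tested, and the 2 tested from the brain, muscle and liver list, miR-124 (-0.63 ± 0.27) and miR-128 (-0.42 ± 0.21), did not pass. Of 8 tested names traced to other RNA classes 1 fell (0 adjusted over the list alone), of 13 G-rich or low-specificity probes 1 fell, and of 9 star strands 1 rose and 1 fell. None of these lists was called by camera. The calls depended on the scaling and the background correction. With the 75th percentile taken over all human miRNAs 2 rose and 1 fell, although differences such as those of miR-92a (-1.29), miR-18b (-1.37), miR-19b (-1.28) and miR-20a (-1.35) stayed near their size. At most 17.7% of all human miRNAs were detected on an array, so that percentile lies in the range of undetected ones. Without scaling 3 rose and 8 fell, and with normexp background correction 0 rose and 8 fell. Without fraction 3, miR-1308 (-0.54) and miR-29a (-0.51) no longer passed, nor without fraction 5 (-0.68 and -0.50), nor miR-1308 without fraction 6 (-0.69).

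The treatment comparison was repeated within fractions 4 to 7 and within fractions 8 to 11, which lay on separate slides. In fractions 4 to 7, let-7e (1.81 ± 0.31), miR-378* (1.55 ± 0.22) and miR-21 (1.01 ± 0.19) rose, and 7 miRNAs fell, all on the miR-17-92 list, among them miR-18a (-1.84 ± 0.30), miR-19a (-1.56 ± 0.20), miR-19b (-1.42 ± 0.21) and miR-20a (-1.27 ± 0.20). In fractions 8 to 11, let-7e (2.76 ± 0.17) and miR-378 (1.82 ± 0.17) rose and miR-19b (-1.19 ± 0.12), miR-20a (-1.25 ± 0.10) and miR-1915 (-1.22 ± 0.10) fell, while miR-19a, detected on 0 of those 8 arrays, differed by 0.39 ± 0.35 and did not pass. The 3 miRNAs called in both sets were let-7e, miR-19b and miR-20a. All 20 miRNAs called over the 9 fractions, which include these arrays, had the same sign in both sets. Across the 102 miRNAs, which are not independent replicates, the differences correlated with Pearson's r = 0.41 and Spearman's rho = 0.31, and 8 of 64 swaps of treatment labels within fractions gave as large an r (permutation p = 0.125).

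The trend along the gradient asked how the level of miRNAs in the labelled RNA changed over the fractions. Neither scaled nor unscaled values give the amount of a miRNA in a fraction, since each array held the same mass of RNA. Relative to the miRNAs seen on every array, the steepest falls were those of the haematopoietic miR-142-3p, by 1.00 per fraction (log2), miR-21 by 0.78, miR-19a by 0.75, miR-223 by 0.71 and miR-27a by 0.59. With slide as a factor only miR-27a (-0.26) of these 5 still passed, and the others had slopes of 0.02 (miR-142-3p), -0.23 (miR-21), -0.11 (miR-19a) and -0.02 (miR-223). The unscaled signal of miR-142-3p dropped from 5874 in control fraction 3 to 147 in control fraction 7 and 1.36 in control fraction 8. Rising relative shares were found for miR-1274b (0.51 per fraction) and miR-720 (0.33), names since traced to transfer RNA, for miR-923 (0.47), traced to ribosomal RNA, and for let-7b (0.35). Of these, miR-1274b, miR-720 and miR-923 were detected on every array and so were themselves in the scaling set of 18. A scaling set without them was not run. With slide as a factor miR-1274b (0.15, adjusted p = 0.269) and miR-923 (0.18, adjusted p = 0.585) no longer passed.

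In all, 32 miRNAs rose and 29 fell along the fractions at a limma adjusted p under 0.05. This fit treats the control and VitD3 arrays of a fraction as independent. Their steps were partly shared (r = 0.75 from fraction 7 to 8), so its p-values are likely too small. Without scaling, where each array stands for the same labelled mass of RNA, 0 rose and 72 fell, and the median slope was -0.33 per fraction against 0.00 with scaling. The 10 largest rising slopes were those named above and miR-940 (0.36), miR-191* (0.32), miR-1228 (0.30), miR-320d (0.28), miR-1238 (0.28) and miR-664 (0.28). With slide as a factor 6 of these 10 passed, and miR-1274b, miR-923, miR-320d (0.21) and miR-664 (0.21) did not. Unscaled, 0 of these 10 passed as rising, and let-7b had a slope of -0.11 (adjusted p = 0.183) and miR-1274b of 0.06 (adjusted p = 0.705). The unscaled signal in control fractions 3 and 11 was 11.9 and 11.5 for miR-1228, and 9.86 and 9.48 for miR-191*. The value used for scaling fell from 1432 to 32.2 between these arrays. Their scaled slopes thus rose as that value fell, and slide as a factor does not remove this. The 10 largest falling slopes included miR-20b (-0.55 ± 0.07 SE), miR-19b (-0.54 ± 0.06), miR-1308 (-0.52 ± 0.08), miR-142-5p (-0.43 ± 0.06) and miR-26b (-0.42 ± 0.05), and were negative without scaling too (-0.78 for miR-142-5p and miR-26b). With normexp miR-1308 (0.00327), miR-142-5p (0.0446) and miR-26b (0.0568, adjusted p = 0.0302) had positive slopes instead. Normexp values carry the offset of 50 and were then scaled, so dim miRNAs can rise where the scaling value falls. A positive slope of a dim miRNA there is therefore not evidence of a rise.

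**Figure D3:**
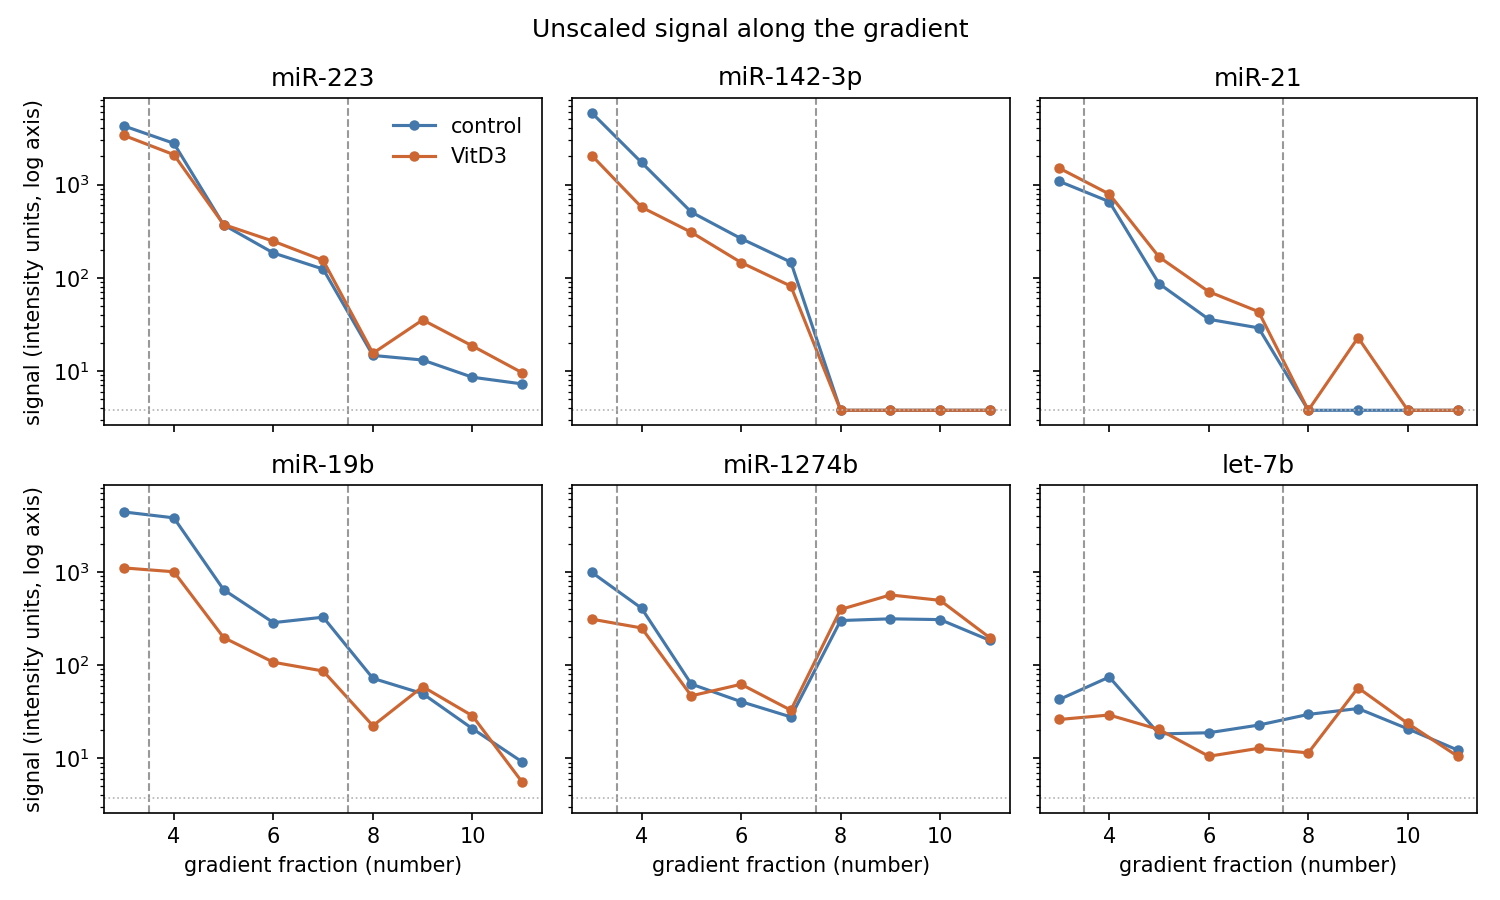
Unscaled signal (intensity units, log axis) of 6 miRNAs against gradient fraction in control and VitD3 cells, 1 point per array, with dashed lines where the slide changes and a dotted line at the floor of 3.78, where lower values are drawn. From fraction 7 to 8 of the control cells, miR-142-3p went from 147 to below the floor and miR-1274b from 27.8 to 301.

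Of 7 tested myeloid miRNAs 6 fell along the gradient, also adjusted over the list alone, with a median slope of -0.43 (unscaled -0.78, with normexp -0.08, camera adjusted p = 0.0029, fry adjusted p = 1.52e-06). With an estimated correlation its adjusted p was 0.427. Of 12 miR-17-92 members 9 fell and miR-18b rose, also adjusted over the list alone (median -0.23, or 0.02 with normexp, camera adjusted p = 0.00285, and adjusted p = 0.427 with an estimated correlation). Of 9 let-7 members 5 rose and 4 did not pass, also adjusted over the list alone (camera adjusted p = 0.0238, and adjusted p = 0.427 with an estimated correlation). The let-7 median was 0.13 with scaling, -0.29 without and -0.11 with the 75th percentile over all human miRNAs. Of 6 monocytic miRNAs 4 fell and miR-29a rose. With scaling the members of miR-15/16 divided, with miR-15a (0.14) and miR-15b (0.11) rising and miR-16 (-0.39) and miR-424 (-0.28) falling. Unscaled, miR-15a (-0.32) and miR-15b (-0.35) fell instead, and with slide as a factor 0 of the 4 members passed. Of 8 names traced to other RNA classes 4 rose and 2 fell, of 13 G-rich or low-specificity probes 4 rose, and of 9 star strands 3 rose and 2 fell. From miR-23/24/27 2 of 3 fell, from miR-29 1 rose and 1 fell, from miR-221 and its relative 1 of 1 fell, from the brain, muscle and liver list 2 of 2 rose, and of 3 miR-181 and 1 miR-30 members 0 passed. The counts of these lists were the same adjusted over the list alone. With slide as a factor 1 of the 6 falling myeloid members (miR-27a) and 1 of the 9 falling miR-17-92 members (miR-19b) still fell, and 1 of the 5 rising let-7 members (let-7b) still rose. In that fit 0 of the 6 monocytic members and 0 of the 2 from the brain, muscle and liver list passed. Of the 13 G-rich or low-specificity probes 9 rose in it, 4 of them also without slide.

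Slide followed fraction, and this bears on the trend. With slide as a factor 27 rose and 3 fell, of which 12 and 2 were among the 32 rising and 29 falling without it, and the 3 that fell were miR-106b, miR-27a and miR-19b. Within fractions 4 to 7, on 1 slide, 21 rose and 4 fell, with miR-21 (-0.39), miR-27a (-0.31) and miR-223 (-0.28) among those falling, and 41 had an unadjusted p under 0.05. Within fractions 8 to 11 0 passed with limma, and 23 had an unadjusted p under 0.05. Of the 29 miRNAs falling over all fractions, 23 had a negative slope within fractions 4 to 7 and 20 within fractions 8 to 11, where 14 lay at the floor on over 0.5 of the arrays and could hardly show one. Few calls within a slide therefore do not show that these slopes were absent there. Without fraction 3 the slope of miR-923 was 0.22 and did not pass.

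**Figure D4:**
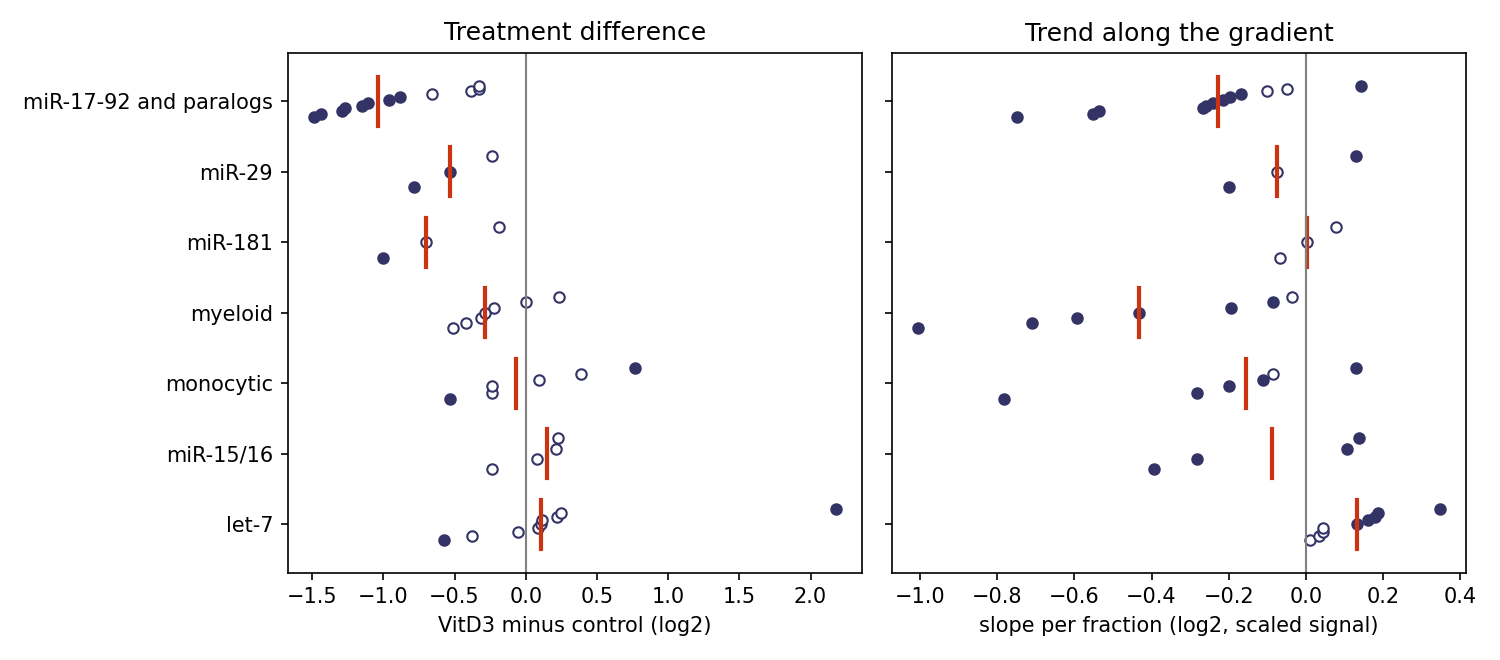
Treatment difference (left, VitD3 minus control, log2) and slope per fraction of scaled signal (right, log2) of the tested members of 7 lists, 1 point per miRNA, filled where the limma adjusted p was under 0.05, with a red bar at the list median. The median of the miR-17-92 list lies at -1.04 on the left and that of the myeloid list at -0.43 on the right, and without scaling the let-7 median on the right changes from 0.13 to -0.29.

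The last comparison asked whether the trend along the gradient differed between treatments. The slope of miR-20a* was higher in VitD3 than in control cells by 0.30 ± 0.06 per fraction (log2, SE, adjusted p = 0.0289), and that of let-7e by 0.25 ± 0.06 (adjusted p = 0.0381). The values of let-7e in control cells lay mostly at the floor, and its trend difference was -0.0308 with the floor lowered to 0.25 of its value and 0.14 (adjusted p = 0.284) without scaling, while that of miR-20a* was -0.0362 with normexp. For miR-20a* 10 values lay at the floor, and it was detected on 5 control and 2 VitD3 arrays. Its treatment difference was -2.00 to -0.50 in fractions 3 to 7. In fractions 8, 10 and 11 it was 0, with both arrays at the floor. In fraction 9, with the high background in VitD3, it was 0.79. Its higher slope thus cannot be told apart from a lower level that reaches the floor. The slopes of miR-638 (-0.34 ± 0.06, adjusted p = 0.0117) and miR-1915 (-0.19 ± 0.04, adjusted p = 0.0381), both G-rich sequences, were lower in VitD3 with scaling. Without scaling these differences were 0.0265 and 0.0905, and that of miR-1915 was 0.0108 with the brightest probe only. In control cells miR-638 had a slope of 0.23 and in VitD3 cells of -0.11. All other miRNAs of the 102 tested fell short, and over all 102, these 4 included, 19 had an unadjusted p under 0.05. Without fraction 10 or 11, 0 of the 4 calls were kept, and 1 was kept without fraction 3, 4 or 8. Camera called the miR-17-92 list up (adjusted p = 0.0195, median 0.05) and the G-rich list down (adjusted p = 0.0188, median -0.17, or 0.09 without scaling), and neither call held with an estimated correlation (adjusted p = 0.763 for both). Without scaling 32 miRNAs had a higher slope in VitD3 and 0 a lower one. The unscaled signal of the arrays was itself lower in VitD3 in each of fractions 3 to 8 and higher in each of fractions 9 to 11. On simulated data the test found 4 of 20 trend differences of 1.5 log2 units over the gradient.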

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

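The tests of RNA load, of the scaling set, of sequence families and of array position for the miR-17-92 pattern, those of RNA load and of the share of calls for the fraction 9 array, and the 8 swaps within each set of 4 fractions, were chosen after the results were seen. The other tests in this part were planned before their results were seen.

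The lower values of the miR-17-92 family after VitD3 are the first pattern, though unscaled the list's median was below 0 in 6 of 9 fractions only. Uniformly weaker labelling of the VitD3 arrays is argued against, since the list's median minus that of the let-7 list, unscaled, was -1.08 on average (exact permutation p = 0.0039, n = 9 fractions). Members of the list in the scaling set do not account for it, since 8 of the 8 called members were called with a scaling set that held none, and hybridisation within 1 sequence family is argued against by called members in 3 further families (18, 19 and 92). Array position cannot be told apart from treatment, since controls and VitD3 arrays lay in separate array columns on 3 of 3 slides, and a difference between cultures stays open because the labels name none. A response of the cells to VitD3 is consistent with the -1.08 above but remains a hypothesis, found and tested on the same data.

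Chance scatter from fraction to fraction is an unlikely source of the count of treatment calls over the 9 fractions. Swaps of labels cannot exclude a chance difference between cultures or an effect of array position. Either could be steady over fractions, and steadiness is all that the swaps test. Of 100 drawn swaps of the labels within fractions, 1, the real one, gave 20 or more calls, and the highest other gave 1. Of 100 splits of any kind, 1 gave as many and the highest other gave 9. Within fractions 4 to 7, 1 of 35 splits gave the real 10 calls and the highest other gave 0, and within fractions 8 to 11, 1 of 35 gave the real 5 and the highest other 0, but these splits ignore the pairing by fraction. Swaps within fractions number only 8 in each set, too few for a share under 0.05 (real 10 and 5, in 1 of 8 each, highest other 0). For the trend difference chance cannot be excluded, since 5 of 100 swaps gave the real 4 calls or more and the highest other gave 16. For the number of lists called by camera with a preset correlation chance cannot be excluded either, since 60 of 100 swaps gave the real 1 list or more, up to 2.

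The step between fractions 7 and 8, where the slide changes, is the second pattern. The spread across miRNAs of the step was 1.48 (SD, log2), or 1.66 times the largest spread of a step within a slide (0.89), and the steps in control and VitD3 cells correlated with r = 0.75 across miRNAs. The change in Feature Extraction version as the main source of both steps is argued against. The step from fraction 3 to 4, where the versions change the other way, correlated with it at -0.0044. A version effect on dim values alone is not decided by this. Control signal was 1432 and 1153 in fractions 3 and 4, but 94.5 and 163 in fractions 7 and 8. Slide and gradient position cannot be told apart, since no fraction was on both slides, and a change in complex size at that position stays open and untested. Dim arrays could add to the step and are not decided, since miRNAs detected on all arrays moved 0.567 times as far as the others (median absolute step 0.64 against 1.13). Of 100 orders of the fractions, only the real one gave 61 trend calls or more, and the highest other gave 55. That order kept fractions 3 to 7 apart from 8 to 11, and so followed the slides.

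The VitD3 fraction 9 array had a negative control signal of 142, where the other VitD3 arrays ran from 25.6 to 37.6, and a local background median of 42, against 25 for the next highest VitD3 array. High local background, over 2 times the median of the other arrays, was found at 43.5% of its spots. Of these spots 57.4% lay in the 4 most affected of 16 blocks, where an even spread gives 25%, though these blocks were picked as the highest. The high background was thus uneven but covered a large part of the array. The negative control signal was 3.78 times the highest of the other arrays. This is the value that flagged the array, so it cannot decide whether the array held more RNA. The treatment calls do not rest on it, since 19 of 20 were called without fraction 9. No biological explanation was tested.

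Of 35 groups of values examined for a far sample, 5 held one, where chance gives about 1 in 20. Besides the 2 of the fraction 9 array, the difference of miR-378* was -0.67 in fraction 9, where the nearest other fraction had 0.80. The difference of miR-17 was 0.22 in fraction 9, against -0.79 in the nearest, and that of let-7a was -0.99 in fraction 4, against 0.08. The slope along the gradient differed between treatments by 0.30 for miR-20a*, 0.25 for let-7e, -0.34 for miR-638 and -0.19 for miR-1915, by the interaction test of limma.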

How the results depend on the processing

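The settings named as added below were chosen after the data were seen, and the cause of a change was not tested except where fewer arrays or miRNAs entered a fit. Over fractions left out in turn, the miRNAs higher in VitD3 numbered 4 to 6, those lower 13 to 20, rising slopes 27 to 33, falling slopes 25 to 32, more positive slopes in VitD3 0 to 2 and more negative ones 0 to 5. The signal difference ran from -0.0832 to 0.22, below 0 without fraction 9 (-0.0253) or 10, and the difference in detected miRNAs from -9.13 to -0.50, or 15.2 with the gene mark of Feature Extraction. All 20 treatment calls kept their sign under every scaling, summary, floor, variance model and fraction left out, and 19 of 20 did with normexp. With dim values left out 19 could be fitted and kept their sign, as did the 4 tested by the filter on all 18 arrays. By construction the offset of normexp shrinks differences of dim miRNAs. Since these values were then scaled, it can also turn slopes of dim miRNAs positive as the scaling value falls along the fractions.

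Without scaling, 8 miRNAs were lower in VitD3, 11 of 20 calls were kept, and the median of all tested miRNAs moved from -0.24 to -0.17. There 0 slopes rose and 72 fell, and 32 slopes were more positive and 0 more negative in VitD3. Values that changed sign were miR-342-3p at -0.14 in the treatment comparison, slopes of miR-940 (-0.0266), let-7b (-0.11), miR-720 (-0.12), miR-1228 (-0.0112), miR-320d (-0.18) and miR-1238 (-0.0295), and trend differences of miR-638 (0.0265) and miR-1915 (0.0905). With the 75th percentile over all human miRNAs, 2 were higher and 1 lower in VitD3, with a median of -0.07, 6 slopes rose against 42 falling, and the trend difference had 0 and 0. Quantile normalization gave 2 higher and 7 lower, with a median of -0.10, a trend difference of 0 and 0, and miR-424 at 0.0179. Normexp gave 0 higher and 8 lower, 78 rising and 9 falling, and 0 more positive and 1 more negative, with miR-378 at -0.00899, miR-146a at -0.0619 and miR-342-3p at -0.0459, slopes of 0.00327 for miR-1308, 0.0446 for miR-142-5p and 0.0568 for miR-26b, and a trend difference of -0.0362 for miR-20a*.

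Agilent's summary per miRNA left 1 more positive trend difference. With the brightest probe only, 8 were higher in VitD3, miR-424 was at 0.11 and miR-1915 had a trend difference of 0.0108. Among miRNAs detected on all 18 arrays, where fewer were tested, 0 were higher and 5 lower, 10 slopes rose and 5 fell, and the trend difference had 0 and 0. With no filter, 1 was higher and 7 lower, and the trend difference had 0 more positive and 1 more negative. With a floor lowered to 0.25 of its value the trend difference had 0 and 0, with let-7e at -0.0308, and with an intensity trend in eBayes 1 more positive. In the authors' value table, in z-score units, the treatment comparison had 0 and 0 past limma's threshold, 3 slopes rose and 147 fell, and the trend difference had 0 and 0. Slopes that changed sign there were miR-1274b (-0.10), miR-923 (-0.10), miR-940 (-0.15), let-7b (-0.22), miR-720 (-0.22), miR-191* (-0.12), miR-1228 (-0.12), miR-320d (-0.20), miR-1238 (-0.14) and miR-664 (-0.0698), with trend differences of -0.18 for let-7e and 0.009 for miR-1915.

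Without the fraction block 3 were lower in VitD3. Fractions 4 to 7 alone gave 7 lower, with miR-424 at 0.0463, and 21 rising and 4 falling slopes. Fractions 8 to 11 alone gave 2 higher and 3 lower, with miR-223 at -0.00595, and 0 rising and 0 falling slopes, with changed signs for miR-923 (-0.17), miR-320d (-0.11), miR-142-3p (0.0528), miR-223 (0.23) and miR-1308 (0.0589), and miR-26b at 0 because its values lay at the floor. With slide as a factor 3 slopes fell, and that of miR-142-3p was 0.0196. The interaction with slide sets in place of fraction number gave 0 and 0. Of the added settings, leaving out values not well above background gave 2 higher in VitD3, 16 falling slopes and a trend difference of 0 and 0, a scaling set without miR-17-92 members 1 more positive trend difference, and fractions 3 to 7 only 8 falling slopes, a slope of -0.11 for miR-1274b and a trend difference of 0 and 0. Arrays weighted by their fit, also added, gave 5 higher and 23 lower.

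In the sets of fractions 4 to 7 and 8 to 11, no scaling gave 23 lower in the former and 0 higher and 0 lower in the latter, quantile normalization 0 higher and 0 lower in the latter, and miRNAs detected on all 18 arrays 0 higher and 3 lower in the former, 0 higher in the latter and a correlation of 0.84. With an estimated correlation camera called 0 lists for the treatment (1 with the preset), 0 up and 0 down for the trend and 0 up and 0 down for the trend difference, and with quantile normalization 0 up and 0 down for the trend difference.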

Other observations

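The comparison of miRNA clusters, and those of detection by treatment and by slide, were chosen after the results were seen, and the tests of neighbouring genes and of brightness before.

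Some miRNAs outside the tested set were seen under 1 treatment alone. miR-630, a low-specificity probe, was detected on 5 of 9 control arrays and 0 of 9 VitD3 arrays (Fisher's exact p = 0.0294), and miR-96 on 3 and 0. Over the 205 miRNAs detected anywhere, 2 had a Fisher's exact p under 0.05 and 0 passed adjustment, the other being let-7e, seen on 1 control and 8 VitD3 arrays (exact p = 0.00337, adjusted p = 0.691). Along the gradient, miR-140-5p, miR-142-3p, miR-199b-5p, miR-19a, miR-21 and miR-29b were detected on all 10 arrays of fractions 3 to 7 and on 0 of the 8 arrays of fractions 8 to 11, with the change of slide between them.

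The 6 members of the miR-17-92 cluster itself (miR-17, miR-18a, miR-19a, miR-20a, miR-19b and miR-92a) may have fallen more than the 3 members of the miR-106b-25 cluster (miR-106b, miR-93 and miR-25), which lies in an intron of the replication gene MCM7. The median of the former differed between treatments by -1.23 on average and that of the latter by -0.42. The difference between the clusters was -0.81 ± 0.13 (log2, SD, n = 9 fractions, exact permutation p = 0.0039, the smallest possible), below 0 in 9 of 9 fractions and also -0.81 without scaling. Hybridisation of miR-17 or miR-20a to the probes of miR-106b and miR-93 would make the clusters more alike. The fall was not particular to the miR-17-92 cluster, since miR-18b (-1.44) and miR-20b (-0.96), which lie in neither cluster, fell too. Genes of miR-19b and miR-92a also neighbour those of miR-18b and miR-20b, so their values do not belong to the miR-17-92 cluster alone. The difference between the clusters is a hypothesis for a test on the primary transcripts, since it was formed from the same values.

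A wider form of this idea, that miRNAs of neighbouring genes change alike, did not pass. Over 34 pairs of different families within 10 kb of each other, the mean absolute difference between treatment changes was 0.38, against 0.58 when values were shuffled over miRNAs (permutation p = 0.0753). The 10 pairs without both members on the miR-17-92 list had 0.59 (permutation p = 0.581). Among these were pairs of miR-20a*, which is not on the list, with list members. One such pair, let-7e and miR-99b*, had changes of 2.18 and 0.65, the latter not past the test. Along the gradient, neighbours were no closer than shuffled miRNAs (0.31 against 0.30, permutation p = 0.624). The slope along the gradient did not follow the brightness of a miRNA (Spearman's rho = -0.0818 across 102 miRNAs, which are not independent), though unscaled slopes had a rho of -0.30.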
